A study of Arabidopsis thaliana with 48 samples.

How the data were processed

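The series measured RNA on Affymetrix ATH1 arrays, which carry 22810 probe sets, in the aerial part of 10-day Landsberg erecta seedlings of Arabidopsis thaliana. Wild-type and gcn2 mutant seedlings were compared after a herbicide, chlorsulfuron (chlorosufuron in the labels), or after solvent alone, called mock here. Per the labels, seedlings were submerged for 1 min at 2 h after light on and incubated for 2 h. The labels state the dose as 0.5 mM and also as a 5 mM stock diluted 10000-fold, which comes to 0.5 µM, so the stated doses lie 1000-fold apart. From each group, total RNA and RNA from a sucrose gradient of 30% to 50% were hybridised, with 4 gradient fractions pooled as non-polysomal RNA, 4 as small polysomes and 4 as large polysomes. Each of the 16 combinations of genotype, treatment and RNA type had 3 replicates, which makes 48 arrays.

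The deposited values are on the log2 scale, and per the submitters' processing notes RMA, the affy package and MAS5 were used; their versions are not given in the sources used here. Whether all arrays were normalized together is not given in the sources used here. Since the arrays, with the exception named next, had similar distributions, only relative changes among probe sets are measured, and a change of all RNAs at the same time is not seen. Array medians ran from 6.145 to 6.311, except for the wild-type mock large polysome array of replicate 1 at 5.668. The SD of probe sets from their group mean was 0.417, 0.363 and 0.583 in the wild-type mock large polysome arrays of replicates 1, 2 and 3, and at most 0.29 in the other arrays. The lower quartile of an array lay between 3.44 and 3.83, and a change from or to a group mean below it is uncertain in size. In a compared group this held in total RNA for AT2G04070, AT3G54150, SWEET4, ECS1, AT4G03156, AT1G35650, AT3G30200, AT4G08680, AT2G13160 and AT1G33130. In at least 1 fraction it held for AT1G43910, AT1G44130, AT3G54150, AT2G20142, AT5G04010, AT1G15180, AT5G39520, AT2G47020, AT1G68250, AT4G03156, AT5G46295, GSTU25 and RSU1. Arrays carry no counts, so the number of arrays limits the precision.

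After 64 control probe sets were left out, 22746 probe sets were tested. Names came from the probe table and the RefSeq annotation of assembly TAIR10.1: 13513 probe sets had 1 gene, 503 had several and 8730 were unnamed here. Among those with 1 gene, 13436 matched through RefSeq and 77 by the probe table only, and they covered 13355 genes. Named genes are given by symbol for 1551 probe sets and by locus for 11962. Counts cover all tested probe sets, and gene names and gene lists cover the probe sets with 1 gene.

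Total RNA was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups and moderated variances (lmFit, eBayes). Polysomal RNA was the mean of the small and large polysome values of a gradient, and polysome loading was that mean minus the non-polysomal value of the same gradient. Both were fitted the same way over 12 gradients. For each, herbicide was compared with mock within each genotype, the difference of these responses was tested as an interaction (gcn2 minus wild type), and gcn2 was compared with wild type within each treatment. For the level of loading in wild-type mock, each gradient was centred on its median and tested against 0. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. Whether replicate numbers pair the samples was tested from correlations of residuals. They did in total RNA (18 of 18 pairs of samples from different groups with the same replicate number, mean correlation 0.37). A fit with the replicate as a block is therefore given beside each total RNA count. These pairs share samples, so they are not independent. In polysomal RNA 15 of 18 pairs passed the correlation of 0.1 that was required of all (mean 0.29). Values of single genes come from the fit without the block unless stated, so genes reported as not passing were judged without it.

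Named genes followed a rule fixed before the data were examined. It took GCN2 and the acetolactate synthase genes CSR1, AT2G31810 and AT5G16290 whatever their values, then the 8 largest rises and the 8 largest falls past the threshold among genes with groups that did not overlap, which chance gives for 10% of genes with 3 against 3. Interactions had no condition on overlap. For each called gene list, or a list with at least 3 members past the threshold, up to 2 rising and 2 falling members were added by smallest adjusted p. For the level of loading, 5 genes per direction were taken.

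Gene lists covered branched-chain amino acid synthesis and breakdown, other amino acid synthesis, aminoacyl-tRNA synthetases, glutathione transferases and xenobiotic response. The breakdown list also holds dark-inducible genes and is called branched-chain amino acid breakdown below. Further lists covered cytosolic and nuclear-encoded plastid ribosomal proteins, and photosystem and light-harvesting proteins. They also covered plastid-encoded and mitochondrion-encoded genes, translation initiation factors, mRNAs with conserved upstream reading frames, jasmonate response, salicylate defence and rapid stress regulators. The remaining lists were heat shock proteins, folding in the endoplasmic reticulum, histones and cell cycle, aliphatic glucosinolates, ATG8 autophagy genes, the circadian clock, root markers and UDP-glycosyltransferases. Lists were fixed before the data were examined, with these exceptions. For the ribosomal protein, aminoacyl-tRNA synthetase, photosystem, mitochondrion-encoded, initiation factor, heat shock and histone lists, the members were entered after the annotation was seen, and the UDP-glycosyltransferase list was added then. Lists with at least 5 measured members were tested by camera with a preset correlation of 0.01 between genes, adjusted over the tested lists of a comparison. Camera with an estimated correlation and fry were run beside it. Many lists were measured only in part, so a list result covers only its measured members. Measured were 11 of 35 glutathione transferases, 8 of 37 histone and cell cycle genes and 5 of 21 xenobiotic response genes. So were 6 of 61 other amino acid synthesis, 9 of 37 plastid ribosomal protein and 7 of 40 photosystem genes. Of 57 list calls, 1 held with an estimated correlation and 11 with fry, whose test does not compare a list with other genes.

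Alternatives were the replicate block, quantile normalization within each RNA type, median centring of each array, leaving out the dimmest 40% of probe sets, a trended and robust prior, array weights, a fit of only the compared groups, an adjusted p under 0.01, an added log2 change of at least 1, leaving out each replicate in turn, small or large polysomes alone, polysomal minus total RNA, and a fit of fraction arrays without pairing. Leaving out wild-type replicate 3 from both arms, alone or with small polysomes alone, and the list tests with small or large polysomes alone were added after seeing the data.

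The fits were tested on simulated data with 100 changed probe sets per size among 22746. Noise was drawn independently for each sample with the same spread in all groups, so replicate pairing, outlying arrays and opposing replicates were not simulated. For the wild-type response of total RNA, 83% of changes of log2 1 and 99% of log2 2 were recovered, with 5 false calls. For the difference of responses in polysome loading, 5% and 73% were recovered, with 4 false calls. No probe set named to GCN2, CSR1 or AT5G16290 alone was in the tables used, and these genes were not analysed here.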

Results

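RNA was profiled in the aerial part of wild-type and gcn2 seedlings 2 h after the herbicide chlorsulfuron or mock treatment. GCN2 is the kinase that phosphorylates the translation initiation factor eIF2α when amino acids run short, and chlorsulfuron inhibits acetolactate synthase, an early enzyme of branched-chain amino acid synthesis. Each of the 4 groups had 3 arrays of total RNA and 3 gradients, each with 1 array of non-polysomal RNA, 1 of small polysomes and 1 of large polysomes. The comparisons address the part of GCN2 in the response to the herbicide at the level of RNA abundance and of polysome loading. Values are log2 with the standard error (SE) and n = 3 per group unless stated. Replicates of a group correlated between 0.929 and 0.9962 across probe sets.

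The mutated gene GCN2 and the herbicide's target CSR1 were named for no probe set of their own in the annotation used and were not analysed here. AT2G31810, a regulatory subunit of acetolactate synthase, had a total RNA change with herbicide of -0.46 ± 0.14 in wild type (adjusted p = 0.055) and 0.02 ± 0.14 in gcn2 (adjusted p = 0.95). Their difference of 0.48 ± 0.19 did not pass (adjusted p = 0.32). In the branched-chain amino acid synthesis list, 4 of 15 genes were measured and 0 passed in either genotype by limma. The other members were AT3G23940, AT3G58610 and ATBCAT-5, with wild-type changes of 0.00, -0.19 and 0.06.

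In wild-type total RNA, 2 h of herbicide raised AT2G41730 most, 13.7-fold (log2 3.77 ± 0.14, adjusted p = 2.6e-10), from 7.87 ± 0.03 (SD, n = 3) to 11.64 ± 0.06. CML38, a calmodulin-like protein, rose by 2.83 ± 0.15 and UGT73C1, a glucosyltransferase, by 2.28 ± 0.18. AT5G52750 (2.65), AT2G32020 (2.32), AT5G52760 (2.31), AT5G20790 (2.17) and AT4G34150 (2.16) completed the 8 largest rises. Falls were smaller. AT4G15680 fell by 1.65 and AT4G15690 by 1.35, both glutaredoxins of the plant-specific CC type. PDF1.4 fell by 1.32, PRN by 1.27, MCCA by 1.22, FU by 1.11, and AT2G15880 and Hsp70-2 by 1.06 each. In all, 1530 probe sets passed, 921 higher and 609 lower, and 3643 passed with the replicate as a block. The count was 947 without herbicide replicate 1, 705 without mock replicate 1 and 670 without herbicide replicate 2.

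The list of branched-chain amino acid breakdown and dark-inducible genes was lower in wild type after herbicide. Of 6 measured, 3 fell and 0 rose (5 fell when adjusted over the list alone), among them MCCA, a subunit of the leucine-degrading methylcrotonyl-CoA carboxylase, and AT5G09300 (-0.74 ± 0.19), of the branched-chain keto acid dehydrogenase. The list median was -0.46, with adjusted p = 0.00014, and adjusted p = 0.061 with an estimated correlation. Xenobiotic response genes were higher, with a median of 0.48 and 2 of 5 rising (3 when adjusted over the list alone): the MATE transporter genes AT2G04050 (1.83 ± 0.19) and AT2G04070 (0.72 ± 0.13). Their adjusted p was 0.0014, and adjusted p = 0.061 with an estimated correlation. Histone and cell cycle genes had a median of 0.42 and 3 of 8 rose (4 when adjusted over the list alone), including the histone H2B genes AT5G02570 (1.46 ± 0.15) and HTB11 (0.54 ± 0.13), with adjusted p = 0.00019, and adjusted p = 0.12 with an estimated correlation. Among the 9 ATG8 genes of autophagy, ATG8E rose (0.96 ± 0.24) and the median was 0.24, with adjusted p = 0.015, and adjusted p = 0.30 with an estimated correlation. Of 122 cytosolic ribosomal protein genes, AT1G15250 rose (0.70) and AT3G55170 (-0.50) and AT3G60770 (-0.44) fell, and the list was not called (median 0.03, adjusted p = 0.27).

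The same herbicide treatment gave larger rises in gcn2 total RNA. AT2G41730 rose by 4.87 ± 0.14 (adjusted p = 5.2e-12), AT5G52760 by 4.71, AT1G43910 by 4.37, AT5G52750 by 4.33 and AT2G32020 by 4.14. STZ, a zinc finger repressor induced by abiotic stress, rose by 4.05 ± 0.16, AT3G60420 by 3.78 and AT3G54150 by 3.69. AT5G57785 fell by 1.89, AT1G62510 by 1.77, AT4G16000 by 1.53 and PYE, a regulator of the iron deficiency response, by 1.44. AT1G03020 (-1.38), AT1G20070 (-1.35), AT1G15370 (-1.34) and AT1G31790 (-1.27) followed. In all, 2626 probe sets passed, 1518 higher and 1108 lower, and 4926 passed with the replicate as a block. The count was 1712 without gcn2 herbicide replicate 2.

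Xenobiotic response genes were higher in gcn2 after herbicide, with a median of 0.70 and 4 of 5 rising, by either adjustment (4 adjusted over the list alone), including AT2G04050 (2.54 ± 0.19) and UGT73B5 (0.85 ± 0.16). The adjusted p was 0.00031, and adjusted p = 0.048 with an estimated correlation. Histone and cell cycle genes had a median of 0.42 and 4 of 8 rose (6 adjusted over the list alone), among them AT5G02570 (1.95) and AT3G53650 (1.24), with adjusted p = 4.6e-05, and adjusted p = 0.11 with an estimated correlation. Of 47 UDP-glycosyltransferase genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone), UGT73C1 by 3.09 ± 0.18 and UGT76E2 by -0.61, with a median of 0.04, adjusted p = 0.038, and adjusted p = 0.92 with an estimated correlation. In branched-chain amino acid breakdown, 4 of 6 fell by either adjustment (4 adjusted over the list alone), ETFQO (-0.54) and MCCB (-0.53) with the smallest adjusted p. The list median was -0.47, with adjusted p = 0.038, and adjusted p = 0.39 with an estimated correlation. Among lists that were not called, AT5G51440, a small heat shock protein gene, rose by 2.16 ± 0.21 while AT2G29500 (-0.62) and AT1G53540 (-0.66) fell. The initiation factor gene AT1G76810 rose (0.64) and AT1G77840 (-0.54) and AT5G35680 (-0.49) fell, and of the cytosolic ribosomal protein genes 1 rose, AT2G32220 (0.50), and 7 fell, including AT4G16720 (-0.67) and AT4G13170 (-0.58). Of 35 listed glutathione transferase genes, 11 were measured, of which 0 rose and 1 fell in gcn2, and 0 passed in wild type.

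Several regulators and folding genes from lists too short to test also passed. STZ rose by 2.00 ± 0.16 in wild type, and WRKY53 rose in gcn2 (1.70 ± 0.21, against 0.62 in wild type, adjusted p = 0.10). BZIP60, a transcription factor of the unfolded protein response, rose by 1.03 ± 0.22 in wild type and 1.75 ± 0.22 in gcn2. ATERDJ3B, a co-chaperone of the endoplasmic reticulum, fell by 0.80 and 0.81, and CRT1b did not pass (-0.36 and -0.33). SAG101, a defence regulator, rose by 0.44 ± 0.11 and 1.30 ± 0.11, and GRX480 rose in wild type (0.71 ± 0.19) and had a value of -0.29 ± 0.19 in gcn2. The clock gene GI, the glucosinolate genes BCAT4 and AT2G31790, and the root markers EXPA7, EXPA18, PYK10 and AT5G17820 did not pass in either genotype, with changes between -0.28 and 0.32. Jasmonate response genes were named for no probe set of their own in the annotation used and were not analysed here.

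**Figure D1:**
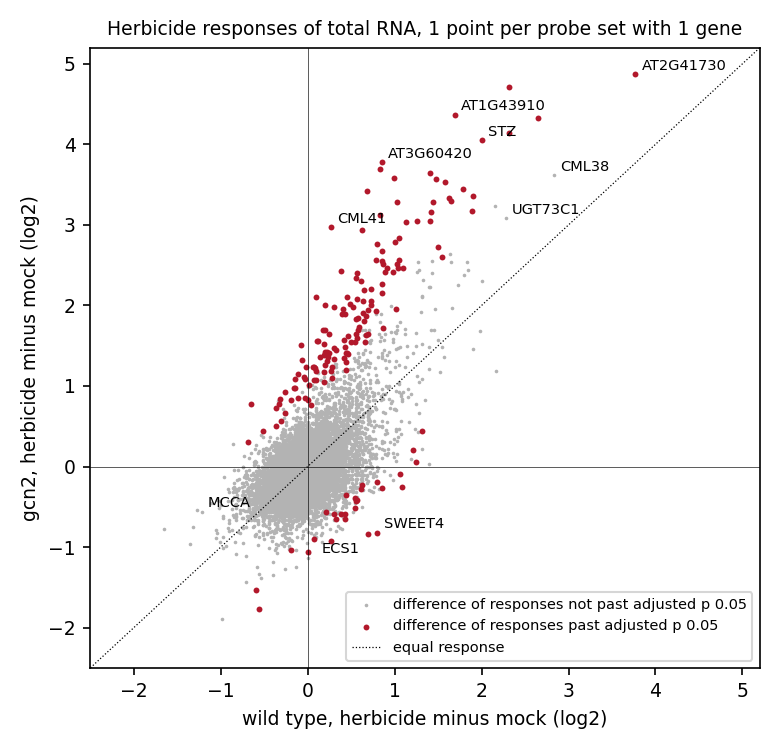
Herbicide minus mock in total RNA (log2) for gcn2 on the y axis against wild type on the x axis, with 1 point per probe set with 1 gene; red points had a different response past an adjusted p of 0.05 and the dotted line marks equal responses. Most red points lie above the line, such as AT3G60420 at 3.78 in gcn2.

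Tested directly, the herbicide response differed between genotypes for 347 probe sets, 299 with a higher and 48 with a lower response in gcn2. Those with the higher response had a median change of 0.55 in wild type and 1.93 in gcn2. AT3G60420 differed by 2.94, AT3G54150 by 2.86, the ERF transcription factor gene AT1G33760 by 2.73 and CML41, a calmodulin-like protein, by 2.70 ± 0.20 (adjusted p = 1.7e-06). CML41 changed by 0.27 ± 0.14 in wild type (adjusted p = 0.29) and rose by 2.97 ± 0.14 in gcn2. AT1G43910 (2.68), AT5G39670 (2.59), AT5G52760 (2.41) and AT4G24110 (2.33) followed, and STZ differed by 2.05 ± 0.23. SAG101 differed by 0.86 ± 0.16 (adjusted p = 0.0096), and for BZIP60, WRKY53 and GRX480 the difference did not pass (adjusted p = 0.36, 0.10 and 0.09). With the replicate as a block 1051 probe sets passed.

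A lower response in gcn2 was seen for SWEET4 and SWEET2, which encode sugar transporters. SWEET4 rose in wild type (0.80 ± 0.19) and fell in gcn2 (-0.82 ± 0.19), a difference of -1.62 ± 0.27 (adjusted p = 0.0035). SWEET2 rose in wild type (1.09 ± 0.17) and had a value of -0.25 ± 0.17 in gcn2, a difference of -1.34. ECS1 differed by -1.53, AT1G62510 by -1.21, AT2G25870 and AT3G52360 by -1.20, AT3G47320 by -1.16 and AT5G02420 by -1.12. The 48 probe sets with a lower response had medians of 0.43 in wild type and -0.59 in gcn2. Plastid-encoded genes had a median difference of -0.27 and mitochondrion-encoded genes of -0.45, and 0 of 69 and 0 of 16 members passed by limma, by either adjustment. Their list tests gave adjusted p = 0.0029 and 0.032, and adjusted p = 0.58 with an estimated correlation for each.

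**Figure D2:**
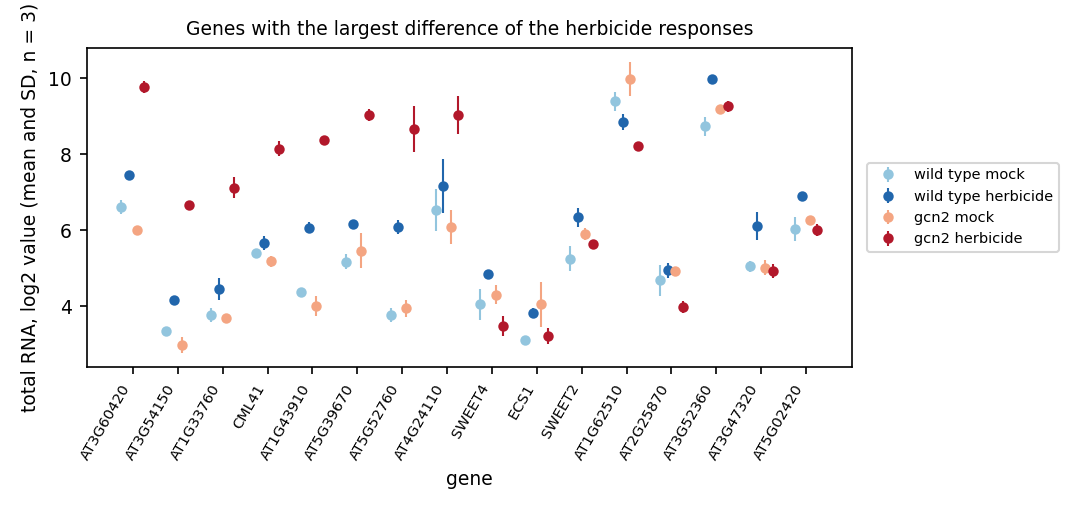
Total RNA (log2, mean and SD, n = 3) in the 4 groups for the 16 genes with the largest difference of the herbicide responses, higher in gcn2 on the left and lower in gcn2 on the right. CML41 reached 8.15 in gcn2 after herbicide and 5.66 in wild type.

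The directions of the responses were shared. Of the probe sets that rose, 602 did so in both genotypes where 61.5 were expected if calls were independent, and 212 fell in both where 29.7 were expected. Across probe sets, which are not independent replicates, the changes correlated with r = 0.622. Probe sets that fell in wild type had a median change of -0.61 there and -0.38 in gcn2, and those that fell in gcn2 had -0.27 in wild type and -0.58 in gcn2. Those that rose in wild type had 0.77 there and 0.83 in gcn2, and those that rose in gcn2 had 0.45 in wild type and 0.86 in gcn2.

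Without herbicide, few genes differed between gcn2 and wild type in total RNA. AT4G03156 was higher in gcn2 by 5.56 (7.73 ± 0.26 against 2.17 ± 0.01, SD, n = 3), AT1G35650 by 4.09, AT1G58025 by 3.63 and QQS, an orphan gene that affects starch content, by 3.16. AT1G35612 (3.11), AT3G30200 (2.07), AT1G42705 (1.38) and AT4G08680 (1.33) were also higher. Wild-type means of AT4G03156, AT1G35650, AT3G30200 and AT4G08680 lay below the lower quartile of the arrays, so the size and order of these differences are uncertain. AT2G04770 was lower by a log2 change of -4.47 and AT2G15560 by -3.73, followed by AT4G12490 (-1.88), AT2G13160 (-1.69), AT2G13430 (-1.44), AT4G22470 (-1.21) and AT2G36885 (-1.07). AT2G13160 lay below that quartile in gcn2 and AT1G33130 in both genotypes. In all 31 probe sets passed, 16 higher and 15 lower, and 163 with the replicate as a block. Of the 26 with a named gene, 23 kept the same sign in all 8 combinations of treatment and RNA type. The 8 include mock total RNA, where these genes were picked, so its sign was largely set by that choice. The cytosolic ribosomal protein list (median -0.07, adjusted p = 0.0067) and the histone list (median -0.21, adjusted p = 0.0067) were lower in gcn2, with 0 members past the threshold by limma by either adjustment, and adjusted p = 0.65 and 0.46 with an estimated correlation. Without replicate 3 of wild type, chosen after seeing the data, the ribosomal protein list did not pass (adjusted p = 0.16).

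After herbicide, 1022 probe sets differed between the genotypes, 699 higher and 323 lower in gcn2, and 2561 with the replicate as a block. The genes that differed in mock led again, with AT4G03156 (5.39) and AT1G35650 (4.34), again from a dim wild-type signal, and AT1G58025 (3.86), AT1G35612 (3.55) and QQS (3.39) higher, and AT2G04770 (-4.51), AT2G15560 (-3.69), AT4G12490 (-1.58), AT2G13430 (-1.29) and AT2G36885 (-1.23) lower. Among 16 probe sets higher in mock, 13 were higher after herbicide too (0.49 expected), and among 15 lower, 11 were lower (0.21 expected). Others belonged to the response, with AT5G39670 (2.87), AT1G33760 (2.67) and AT5G52760 (2.58) higher and SWEET4 (-1.37), AT3G47320 (-1.19) and AT3G02820 (-1.06) lower. Of the cytosolic ribosomal protein genes, 0 were higher and 3 lower (1 adjusted over the list alone), with AT4G16720 (-0.66) and AT2G36160 (-0.54) named. This list (median -0.18, adjusted p = 1.2e-06), the plastid ribosomal protein list (median -0.23, adjusted p = 0.023), the plastid-encoded list (median -0.31, adjusted p = 9.7e-06) and the ATG8 list (median -0.37, adjusted p = 0.0059, APG8H at -0.68) were lower, with adjusted p = 0.56, 0.56, 0.81 and 0.47 in this order with an estimated correlation. The count was 665 without gcn2 herbicide replicate 1, 653 without wild-type herbicide replicate 2 and 613 without gcn2 herbicide replicate 2.

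The wild-type gradients of replicate 3 stood apart from the others. Over the 2626 probe sets that changed in gcn2 total RNA, signed by that direction, herbicide minus mock averaged 0.30 to 0.44 in the fractions of wild-type replicates 1 and 2. In replicate 3 it was -0.30 in non-polysomal RNA, -0.39 in small polysomes and -0.29 in large polysomes, while total RNA of replicate 3 gave 0.41. Comparisons that use the wild-type gradients are therefore given also without replicate 3 in both arms, a choice made after seeing the data.

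**Figure D3:**
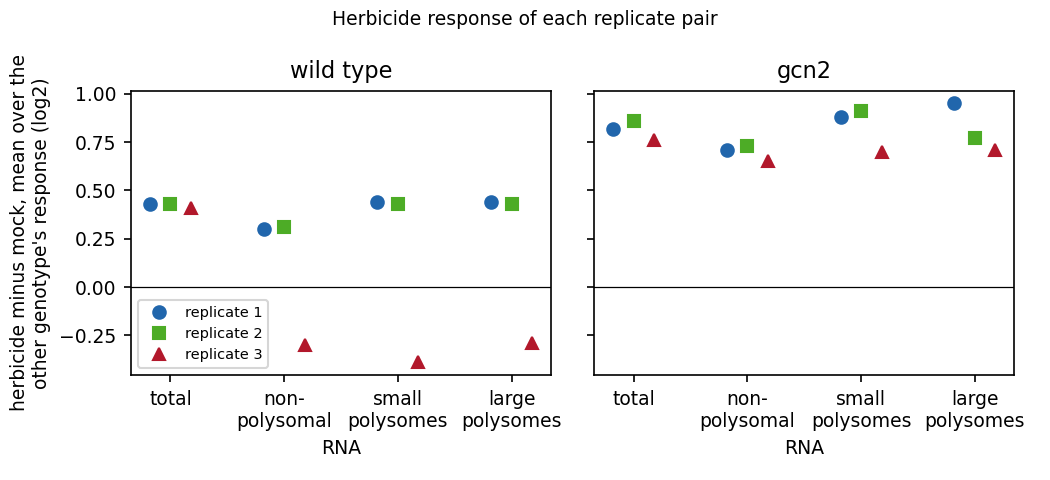
Herbicide minus mock of each replicate pair (log2, y axis), averaged over the probe sets that changed in total RNA of the other genotype and signed by that direction, for total RNA and the 3 gradient fractions (x axis). Wild-type replicate 3 lies at -0.30, -0.39 and -0.29 in the fractions and at 0.41 in total RNA.

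In wild-type polysomal RNA no probe set passed for the herbicide by limma, and 874 had an unadjusted p under 0.05. The smallest p-values belonged to AT5G55380 (0.87 ± 0.23), AT2G41410 (1.19 ± 0.32) and XTH33 (1.23 ± 0.35), each with adjusted p = 0.99. Without replicate 3, 205 passed, 194 higher and 11 lower. The mock large polysome array of replicate 1 had a median of 5.668, against 6.171 in replicate 2. Arrays were not centred for this fit, which favours rises, and the size of this effect was not tested. AT2G41730 then rose by 3.28 ± 0.18, CML38 by 2.49 ± 0.27 and UGT73C1 by 2.47 ± 0.19, and AT4G15680 (-1.33), PDF1.4 (-1.15) and AT4G15690 (-1.0) fell. With all gradients, 7 lists were called higher, with 0 members past the threshold by either adjustment: plastid-encoded genes (median 0.33, adjusted p = 6.3e-09), cytosolic ribosomal proteins (0.17, 1.4e-06), UDP-glycosyltransferases (0.11, 0.0093), histones and cell cycle (0.22, 0.019), and xenobiotic response (0.40), plastid ribosomal proteins (0.17) and mRNAs with conserved upstream reading frames (0.29) at 0.034 each. Each had adjusted p = 0.70 with an estimated correlation, and without replicate 3 cytosolic ribosomal proteins (median -0.01, adjusted p = 0.18), plastid ribosomal proteins (0.05, 0.93) and plastid-encoded genes (0.07, 1) did not pass. The list of conserved upstream reading frames did not pass then either (0.24, 0.21), and xenobiotic response (0.00028), histones (0.0052) and UDP-glycosyltransferases (0.03) did, with adjusted p = 0.074, 0.90 and 0.92 with an estimated correlation.

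Polysomal RNA of gcn2 followed its total RNA. AT1G33760 rose by 3.84 ± 0.23 (adjusted p = 3.2e-07), AT2G41730 by 4.61, AT5G52760 by 4.60, AT5G52750 by 4.27, AT1G43910 by 4.22, AT2G32020 by 4.08, AT1G78410 by 3.71 and CML38 by 3.68. AT1G62510 fell by 1.88, AT5G57785 by 1.51, AT1G03020 by 1.26, OSM34 by 1.23, PYE by 1.18, AT1G20070 by 1.14, ASF1B, a histone chaperone, by 1.08 and AT4G16000 by 1.02. In all 1085 probe sets passed, 873 higher and 212 lower. Of the 873 that rose in polysomes, 794 rose in total RNA too, where 58.3 were expected, and of the 212 that fell, 144 fell in total RNA, where 10.3 were expected. Across probe sets the changes correlated with r = 0.892. The count was 628 without mock replicate 1, 664 without herbicide replicate 2 and 612 without mock replicate 2.

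Among gene lists in gcn2 polysomes, 3 of 8 histone and cell cycle genes rose (5 adjusted over the list alone), including AT5G02570 (2.13) and AT3G53650 (1.35), with a median of 0.52, adjusted p = 9e-06, and adjusted p = 0.22 with an estimated correlation. Xenobiotic response genes had a median of 0.87 and 3 of 5 rose by either adjustment (3 adjusted over the list alone), AT2G04050 by 2.60 and UGT73B5 by 0.87, with adjusted p = 0.00085, and adjusted p = 0.25 with an estimated correlation. UGT73C1 (2.88) and UGT71C5 (0.69) were among 4 of 47 UDP-glycosyltransferase genes that rose (6 adjusted over the list alone), and this list was not called (adjusted p = 0.073). Plastid-encoded genes were lower, with a median of -0.21 and 0 of 69 past the threshold by limma by either adjustment, adjusted p = 0.015, and adjusted p = 0.90 with an estimated correlation.

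The polysomal response differed between genotypes for 93 probe sets, all with a higher response in gcn2. AT3G48650 differed by 3.36 ± 0.66, AT1G33760 by 3.23 ± 0.33, AT5G39670 by 3.11, AT1G78410 by 3.04, AT1G44130 by 3.0, AT3G60420 by 2.97, AT3G54150 by 2.90 and AT2G20142 by 2.80. With the replicate as a block AT3G48650, AT5G39670, AT3G60420 and AT3G54150 did not pass (adjusted p = 0.061, 0.05, 0.058 and 0.058). Without replicate 3, 101 probe sets passed, and AT1G33760 (2.75 ± 0.24), AT2G20142 (2.40), CML41 (2.39) and CCR2, a cinnamoyl-CoA reductase (2.25), were among the largest. Xenobiotic response (median 0.47, adjusted p = 0.025) and histone lists (0.30, 0.0037) had the higher response in gcn2, and plastid-encoded genes (-0.53, 1.5e-09), cytosolic ribosomal proteins (-0.24, 0.0015) and plastid ribosomal proteins (-0.36, 0.025) the lower. In each, 0 members passed by limma (1 xenobiotic response gene higher adjusted over the list alone), and adjusted p = 0.82 with an estimated correlation. Without replicate 3, cytosolic ribosomal proteins (median -0.02, adjusted p = 0.73), xenobiotic response (0.09, 0.27) and plastid ribosomal proteins (-0.24, 0.39) did not pass. Plastid-encoded genes (median -0.31, 0.012) and histones (0.21, 0.012) passed, with adjusted p = 0.84 for each with an estimated correlation. The count was 149 without wild-type mock replicate 1, 40, 33 and 53 without gcn2 herbicide replicates 1, 2 and 3, 30 and 23 without gcn2 mock replicates 1 and 2, and 39 without wild-type herbicide replicate 3.

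In wild-type mock seedlings, RNAs differed widely in polysome loading relative to the median RNA. AT1G64370 (2.56 ± 0.22), AT5G45350 (2.24), AT5G28630 (1.84), psbD (1.76) and AT1G04800 (1.69) were among the most loaded. AT5G55010 (-2.74 ± 0.19), AT5G21020 (-2.48), the ribosomal protein gene AT2G40010 (-2.46), AT1G15180 (-2.38) and the mitochondrial gene ccb382 (-2.34) were among the least. In all 6626 probe sets passed, 2774 above and 3852 below. Mitochondrion-encoded RNAs were the least loaded list, with a median of -1.06 and 9 of 16 below by limma (10 adjusted over the list alone), such as ccb452 (-1.71). Plastid-encoded RNAs had a median of -0.46, with 1 above (psbD) and 19 below (the same adjusted over the list alone), such as psaJ (-2.11) and psbM (-1.25). These lists had adjusted p = 3.9e-06 and 0.0020, and adjusted p = 0.23 and 0.76 with an estimated correlation. Without replicate 3 the plastid-encoded list did not pass (median -0.22, adjusted p = 0.19).

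Aminoacyl-tRNA synthetase mRNAs were more loaded, with a median of 0.44, 10 of 19 above and 1 below (11 and 1 adjusted over the list alone), such as AT5G27470 (1.05) and AT3G62120 (0.98), against AT3G56300 (-1.04). Other amino acid synthesis mRNAs had a median of 0.47 and 3 of 6 above (4 adjusted over the list alone), AT5G66120 (0.98) and AT2G04400 (0.84) among them. Their adjusted p were 0.0013 and 0.013, and adjusted p = 0.23 for each with an estimated correlation. The mRNAs with conserved upstream reading frames, which repress translation of the main frame, had a median of -0.46 with 3 of 5 below (3 adjusted over the list alone), BZIP53 (-0.65) and AT5G15950 (-0.51) among them, and the list was not called (adjusted p = 0.066). Members of other lists went both ways. GSTU25 (0.70) and GSTU20 (0.60) were above and GSTU18 (-0.92) and GSTU28 (-0.69) below. UGT73B4 (0.56) and AER (0.49) were above and AT2G04050 (-0.94) below. AT3G11250 (1.00) and AT5G02870 (0.73) were above and RSU1 (-1.14) below, as part of 8 cytosolic ribosomal protein genes above and 14 below of 122. AT2G04520 (1.02) and AT5G35680 (0.94) were above and AT4G27130 (-0.82) and AT5G54940 (-0.53) below among initiation factors. UGT78D2 (0.69) and UGT84A4 (0.62) were above and UGT71C5 (-0.58) and UGT85A3 (-0.44) below.

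Few genes passed for a change in polysome loading with herbicide, where 49% (wild type) and 45% (gcn2) of simulated changes of log2 1 were recovered. The simulation shifted every herbicide gradient alike, whereas wild-type replicate 3 opposed the others. The 49% may therefore be too high for the real wild-type gradients. In gcn2, 11 probe sets passed, 6 higher and 5 lower, with AT5G52960 (1.77 ± 0.21, adjusted p = 0.0026), AT5G39520 (1.62) and AT2G29020 (1.5) higher and LCR67, a defensin-like protein (-1.87), and AT3G04640 (-1.53) lower. AT2G47020 passed too, but all 3 of its fractions lay below the lower quartile of the arrays after herbicide, so no change is given. Array weights gave 247. With the replicate as a block 7 passed, and LCR67, AT3G04640 and AT2G47020 did not (adjusted p = 0.081, 0.094 and 0.086). Left out in turn, herbicide replicates 1, 2 and 3 gave 1, 0 and 7, and mock replicates 1, 2 and 3 gave 1, 3 and 2. In wild type, 0 passed by limma and 1188 had an unadjusted p under 0.05, with AT5G04010 (-0.95), AT1G15180 (1.24) and AT2G40980 (1.05) at adjusted p = 0.92. Without replicate 3, 1 passed, AT4G29030 (-2.09). For the difference of responses, 0 passed by limma and 1419 had an unadjusted p under 0.05, and the smallest p-values were those of AT5G52960 (1.94, adjusted p = 0.091), OSM34 (-1.85) and LCR67 (-2.15). AT5G16860 (-2.00) was the 1 that passed without replicate 3, and 1 passed without wild-type mock replicate 3 alone.

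Ribosomal protein mRNAs had a higher loading in gcn2 after herbicide than in mock, with medians of 0.23 for 122 cytosolic and 0.32 for 9 plastid ribosomal protein genes (adjusted p = 9.4e-06 and 0.018), while plastid-encoded RNAs had a lower one (median -0.36, adjusted p = 9.4e-06). In wild type the cytosolic list was not called (median -0.02, adjusted p = 0.16), the ATG8 list was lower (-0.17, adjusted p = 0.0099) and the UDP-glycosyltransferase list higher (0.20, adjusted p = 0.0046). The responses differed (gcn2 minus wild type) for cytosolic (0.21, adjusted p = 4.3e-06) and plastid ribosomal proteins (0.49, 0.0034), plastid-encoded genes (-0.39, 0.0010), ATG8 genes (0.31, 0.011) and UDP-glycosyltransferases (-0.20, 0.0040). In every list of these 3 comparisons 0 members passed by limma, and adjusted over the list alone 1 plastid-encoded and 1 other amino acid synthesis gene were lower in gcn2 and 1 UDP-glycosyltransferase gene lower for the difference. With an estimated correlation, the list tests gave adjusted p = 0.76 in gcn2, 0.73 in wild type and 0.64 for the differences. Without replicate 3, cytosolic ribosomal protein mRNAs had a lower loading in wild type after herbicide, with a median of -0.47 and 114 of 122 negative (adjusted p = 5.4e-26, and adjusted p = 0.031 with an estimated correlation). Their difference of responses was then 0.65 (adjusted p = 1.7e-33, and adjusted p = 0.016 with an estimated correlation). That of plastid-encoded genes did not pass (-0.31, adjusted p = 0.24). Wild-type replicate 3 opposed the others in the cytosolic list, so leaving it out enlarges both cytosolic values by construction. They rest on 2 wild-type gradients per arm. In mock replicate 3 this list lay at -0.16 with small polysomes alone and -1.57 with large polysomes alone.

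**Figure D4:**
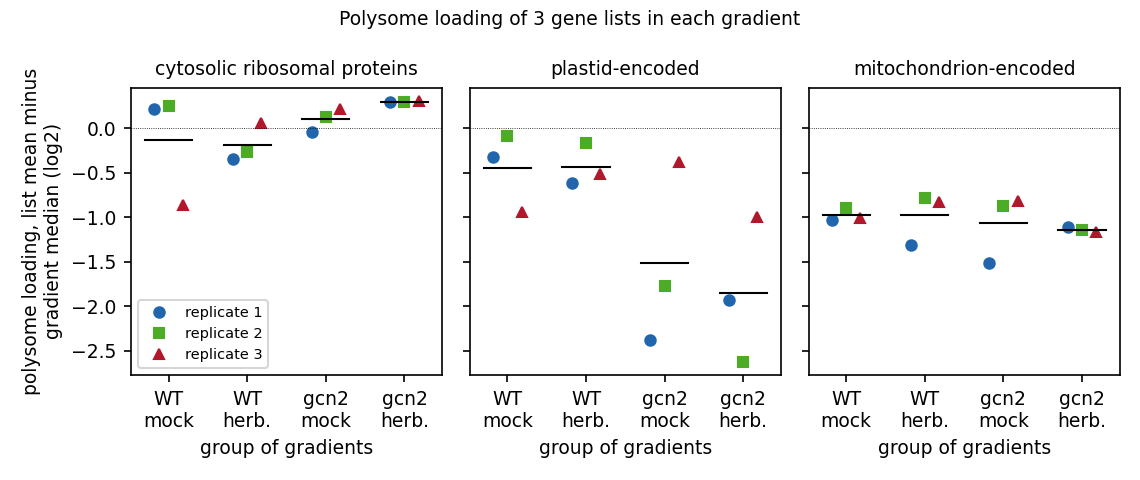
Polysome loading of 3 gene lists in each gradient (list mean minus the gradient's median, log2, y axis) by group of gradients (x axis), with replicates as symbols and the group mean as a bar. Cytosolic ribosomal proteins of wild-type replicate 3 lie at -0.86 in mock and 0.06 after herbicide, against 0.21 and 0.25 and against -0.35 and -0.27 in replicates 1 and 2.

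Between genotypes, plastid-encoded RNAs had a lower loading in gcn2. The list mean was -1.51 ± 1.02 (SD, n = 3) in gcn2 mock against -0.45 ± 0.44 in wild type, and -1.85 ± 0.82 against -0.44 ± 0.23 after herbicide. The median difference was -0.80 in mock and -1.23 after herbicide, with 0 of 69 members past the threshold by limma in each (24 and 54 lower adjusted over the list alone). An exact permutation test of the gradients within treatments gave p = 0.02 (two-sided) for the mean difference of -1.24, and 0.16 adjusted over the lists. By camera, adjusted p = 3.4e-24 and 3.4e-35, and adjusted p = 0.67 and 0.31 with an estimated correlation. By RNA type it was largest in non-polysomal RNA, where the list was higher in gcn2 by 1.19 (exact permutation p = 0.01). Adjusted over the lists, this did not pass either (0.08). Small polysomes (-0.20), large polysomes (0.01) and total RNA (-0.17) had exact permutation p = 0.26, 0.98 and 0.36. Non-polysomal values of gcn2 replicate 3, 3.45 in mock and 3.73 after herbicide, lay near those of wild type (3.13 to 3.38 and 3.31 to 3.75).

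After herbicide, ribosomal protein mRNAs were more loaded in gcn2 than in wild type, with medians of 0.49 for cytosolic (0 members past the threshold and 34 higher adjusted over the list alone) and 0.68 for plastid ribosomal proteins (0 and 7). Adjusted p was 4.5e-22 and 7.9e-09, and adjusted p = 0.47 and 0.31 with an estimated correlation. Without replicate 3 the medians were 0.63 and 0.85, with adjusted p = 0.016 and 0.019 with an estimated correlation. Polysomal RNA of these lists was not higher in gcn2. After herbicide, the cytosolic list differed by -0.65 in non-polysomal RNA, -0.09 in small and -0.22 in large polysomes, and the plastid list by -1.12, -0.26 and -0.40. Over both treatments, exact permutation of the gradients gave p = 0.1 and 0.05 for loading, 0.27 and 0.16 adjusted over the lists. The photosystem (0.25, adjusted p = 0.017), histone (0.29, 0.041) and ATG8 lists (0.25, 0.041) were also more loaded, and aminoacyl-tRNA synthetases (-0.31, 0.0039, 1 lower adjusted over the list alone) and branched-chain amino acid breakdown (-0.39, 0.027) less. Adjusted p = 0.47, 0.64, 0.62, 0.47 and 0.51 in this order with an estimated correlation. In mock, cytosolic (0.26, adjusted p = 2.8e-06) and plastid ribosomal proteins (0.22, 0.022) and UDP-glycosyltransferases (0.13, 0.044) were more loaded in gcn2, with adjusted p = 0.67 for each with an estimated correlation, and without replicate 3 the cytosolic list was lower (median -0.04, adjusted p = 0.0020, and adjusted p = 0.53 with an estimated correlation) and the plastid ribosomal protein list did not pass (0.09, adjusted p = 0.61).

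Of single genes, 2 probe sets passed for loading between genotypes in mock, AT4G03156 and AT1G68250. In 1 genotype each, wild type and gcn2, all 3 of their fractions lay below the lower quartile of the arrays, so no difference in loading is given. AT2G04770 was next (1.58, adjusted p = 0.082). After herbicide 32 differed, 26 higher and 6 lower in gcn2. AT5G52960 (1.86), AT2G29020 (1.71), AT5G11340 (1.6), AT2G04770 (1.58), AT2G11910 (1.36), AT3G15900 (1.26), AT1G48440 (1.25) and AT5G46295 (1.24) were higher, and LCR67 (-2.13), AT1G26690 (-1.27) and BGLU33 (-1.05) lower. AT4G03156 passed too, with the same dim wild-type signal. With the replicate as a block 7 passed, and AT5G11340, AT2G04770, AT2G11910, AT3G15900, AT1G48440, AT5G46295, AT1G26690 and BGLU33 did not (adjusted p from 0.054 to 0.09), while array weights gave 2078. Without replicate 3 in both arms, 4 differed in mock and 765 after herbicide, 588 higher and 177 lower. Among the 765 were 42 of 122 cytosolic ribosomal protein genes, all higher. Wild-type mock gradients enter the herbicide comparison only through the spread shared by all groups. Leaving out wild-type herbicide replicate 3 alone gave 13, so the 765 depends on taking mock replicate 3 out of that spread. In mock, leaving out wild-type mock replicate 3 gave 4, and leaving out each of the other mock replicates gave 1. After herbicide it gave 2, 5 and 13 without wild-type replicates 1, 2 and 3, and 7, 3 and 68 without gcn2 replicates 1, 2 and 3.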

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

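Chosen only after the results were seen were the 3 tests on the wild-type replicate 3 gradients, the tests of exposure and of normalization, the 2 tests of plastid-encoded RNAs that leave out arrays, and the regroupings of genotypes; the permutation of gradients between genotypes and the other regroupings of samples were set before.

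The wild-type gradients of replicate 3 responded opposite to replicates 1 and 2, with scores of -0.30, -0.39 and -0.29 in non-polysomal RNA, small polysomes and large polysomes. A weak response of these plants needs scores near 0, but their mean of -0.33 lay below -0.16. Here 0.16 was the largest score of 36 differences between replicates of the same treatment. Differences of wild-type fractions that involve replicate 3 were left out of these 36, so the bound was set without the gradients it judges. An outlying mock large polysome array (SD from its group mean 0.583) would leave the other fractions in place, but the higher of their scores was -0.3. An exchange of the mock and herbicide gradients is a candidate explanation: the highest score was -0.29, and on a scale from 0 (mock of replicates 1 and 2) to 1 (herbicide) the gradient labelled herbicide lay at -0.06, 0.04 and 0.11 and the gradient labelled mock at 0.92, 0.93 and 0.78. The bound of 0.16 was set after the scores were seen, in place of 0.32, within which -0.30 and -0.29 would lie. That 0.32 came from gcn2 over another gene set, where the gcn2 fractions responded by 0.65 to 0.95, so the scales differ. Since the bound was chosen late, the exchange stays a hypothesis. No sample was relabelled and no biological explanation was tested.

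The response of total RNA differed between genotypes for 347 probe sets, with most of them higher in gcn2 after herbicide. A uniformly stronger exposure of gcn2 would enlarge falls as well as rises. For genes picked in 1 wild-type pair and measured in the others, the ratio of gcn2 to wild type was 1.31 to 1.38 for rises. For falls it was at most 0.823, but picking in wild type favours genes that fall there. Probe sets that fell in gcn2 had medians of -0.58 there and -0.27 in wild type, but picking them in gcn2 from the same arrays favours larger falls there. Those that fell in wild type went the other way, with -0.61 there and -0.38 in gcn2. Neither pick can decide the question, so a stronger exposure was not excluded. With other normalizations of the deposited values the count was 348 or more. Medians of the total RNA arrays already lay between 6.212 and 6.246, so these steps changed little and cannot decide whether the original normalization played a part. Chance was not excluded: 7 of 100 regroupings of treatment within each genotype and 5 of 100 regroupings of genotype within each treatment gave as many probe sets, with the highest other counts at 4178 and 569, and 3 of 17 and 1 of 13 among those that part as many replicate pairs (highest other 4178 and 229). The regroupings keep the herbicide response, and the treatment regroupings with the most genes reversed it for all or most samples of 1 genotype, a structure of the samples, so they are no clean measure of chance; with the replicate as a block 1051 passed, and an effect of the missing GCN2 may remain as a hypothesis.

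Plastid-encoded RNAs had a lower polysome loading in gcn2, with a mean difference of -1.24. Chance assignment of gradients to genotypes gave a difference as large in 8 of 400 splits, with 1.22 the next largest in size, although this exact permutation test gave p = 0.16 when adjusted over the lists. Without wild-type replicate 3 the list median kept at least 0.992 of its size in both treatments, and with small polysomes alone, which leaves out the 3 outlying large polysome arrays of wild-type mock, at least 1.08. The gcn2 gradients of replicate 3 lay at -0.38 in mock and -1.0 after herbicide, and wild-type gradients at -0.94 to -0.09, so the genotypes overlapped in mock. By RNA type the difference was largest in non-polysomal RNA (1.19, exact permutation p = 0.01, and 0.08 adjusted over the lists, which did not pass). A change in translation of plastids and a different recovery of plastid RNA at the top of the gradient both stay open, and neither was tested.

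Other results stood out because a test of the difference between genotypes called them. In total RNA these were AT3G60420 (2.94), AT3G54150 (2.86), AT1G33760 (2.73), CML41 (2.70), AT1G43910 (2.68), AT5G39670 (2.59), AT5G52760 (2.41) and AT4G24110 (2.33), and SWEET4 (-1.62), ECS1 (-1.53), SWEET2 (-1.34), AT1G62510 (-1.21), AT2G25870 (-1.20), AT3G52360 (-1.20), AT3G47320 (-1.16) and AT5G02420 (-1.12). In polysomal RNA 93 probe sets differed, with AT3G48650 (3.36), AT1G33760 (3.23), AT5G39670 (3.11), AT1G78410 (3.04), AT1G44130 (3.0), AT3G60420 (2.97), AT3G54150 (2.90) and AT2G20142 (2.80) the largest. Gene lists with a called difference were, by their medians, plastid-encoded (-0.27) and mitochondrion-encoded genes (-0.45) in total RNA. In polysomal RNA they were xenobiotic response (0.47), cytosolic ribosomal proteins (-0.24), plastid ribosomal proteins (-0.36), plastid-encoded genes (-0.53) and histones (0.30). Of these, xenobiotic response and both ribosomal protein lists did not pass without wild-type replicate 3. In polysome loading the called lists were cytosolic (0.21) and plastid ribosomal proteins (0.49), plastid-encoded genes (-0.39), ATG8 genes (0.31) and UDP-glycosyltransferases (-0.20). Plastid-encoded genes did not pass there without wild-type replicate 3. With an estimated correlation between genes no list passed, with adjusted p = 0.58 in total RNA, 0.82 in polysomal RNA and 0.64 in loading.

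For comparisons of 3 samples with 3, the 10 splits are too few for a share under 0.05. In total RNA, 1 of 10 splits, the real one, gave as many probe sets for the herbicide in wild type (1530, highest other 0) and in gcn2 (2626, highest other 1, and 0 among splits that part as many replicate pairs). The same held for the genotypes in mock (31, highest other 0) and after herbicide (1022, highest other 0), in gcn2 polysomal RNA (1085, highest other 0), and for loading between genotypes in mock (2, highest other 0) and after herbicide (32, highest other 0). For loading in gcn2, 2 of 10 splits gave at least the real 11, with 46 in the other. In wild-type gradients the real split gave 0, so 10 of 10 splits gave as many in polysomal RNA and in loading, and the split that exchanged the replicate 3 gradients gave 426 and 1435, which points to a structure of the samples. For the difference of responses in polysomal RNA chance was not excluded: 13 of 100 treatment regroupings (highest other 2033) and 9 of 100 genotype regroupings (highest other 406) reached the real 93, with the same limit. In loading the real count was 0, so that all 100 of 100 reach it says nothing, and the highest other was 430. The regroupings with 2033 and 430 exchanged wild-type replicates 1 and 2 and left replicate 3 and gcn2 in place.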

How the results depend on the processing

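The alternatives chosen only after the data were seen were those that leave wild-type replicate 3 out of both arms and the list tests with small or large polysomes alone. Counts are given where they moved by more than 1.5 times, or to or from 0, with the count reported above in brackets at first mention. Other counts stayed within 1.5 times under the alternatives run for them, and the cause was not tested unless stated.

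With the replicate as a block, total RNA gave 3643 (1530) for the herbicide in wild type, 4926 (2626) in gcn2, 1051 (347) for the difference of responses, 163 (31) between genotypes in mock and 2561 (1022) after herbicide. It gave 1685 (1085) in gcn2 polysomes, and in loading 7 (11) for gcn2, 1 (2) between genotypes in mock and 7 (32) after herbicide. The stricter adjusted p under 0.01 lowers counts by construction. It gave, in the same order, 555, 1412, 189, 20 and 540 in total RNA, 549 in gcn2 polysomes, 23 (93) for the difference in polysomes, and 1, 1 and 6 in loading, with 4143 (6626) for the level of loading. An added log2 change of 1, also stricter, gave 271, 654 and 284 for the responses and the herbicide genotype difference in total RNA, 623 in gcn2 polysomes and 1196 for the level.

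Array weights gave 58 between genotypes in mock and 1717 after herbicide in total RNA, and 2627 in gcn2 and 184 for the difference in polysomes. In loading they gave 247 in gcn2, 20 (0) for the difference, and 5 and 2078 between genotypes in mock and after herbicide. Without dim probe sets, which tests fewer genes, counts were 14 between genotypes in mock in total RNA, 40 for the difference in polysomes, and 1 and 94 between genotypes in loading. With only the compared groups in the fit, loading gave 17 in gcn2, 1 and 476 between genotypes, and 3184 for the level. Median centring gave 210 for the difference in polysomes, and 7 in gcn2 and 1 for the difference in loading; it moved the median of all probe sets for loading in wild type to -0.103. Quantile normalization gave 1 for the difference in loading. A trended and robust prior kept all 14 counts within 1.5 times.

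Large polysomes alone gave 402 in gcn2 and 14 for the difference, and relative to non-polysomal RNA 1 in gcn2 and 1 and 2 between genotypes. Small polysomes alone gave 174 for the difference, and relative to non-polysomal RNA 19 in gcn2 and 215 between genotypes after herbicide. Polysomal minus total RNA gave 0 in gcn2 by limma, and 1 and 1 between genotypes. Fraction arrays fitted without pairing gave 1 in gcn2 and 1 and 2 between genotypes.

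Without wild-type replicate 3 in both arms, total RNA gave 632 for the wild-type response, 216 for the difference, and 18 and 634 between genotypes, with fewer samples. Wild-type polysomes gave 205 (0), and loading 1 (0) in wild type, 1 (0) for the difference, and 4 and 765 between genotypes. The 765 after herbicide depends on mock replicate 3 leaving the spread shared by all groups. With small polysomes alone as well, the values were 145 for wild-type polysomes, and 0 by limma and 482 for loading between genotypes. Camera's direction relative to other genes turned for 6 lists. The median changed sign for cytosolic ribosomal proteins in wild-type polysomes (-0.01, adjusted p = 0.18) and in loading between genotypes in mock (-0.04, 0.0020). It kept its sign for plastid ribosomal proteins (0.05, 0.93) and plastid-encoded genes (0.07, 1) in wild-type polysomes, cytosolic ribosomal proteins in the difference in polysomes (-0.02, 0.73) and plastid ribosomal proteins in loading in mock (0.09, 0.61).

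Leaving out each replicate in turn, with fewer samples, gave 670 to 1368 for the wild-type and 1712 to 2540 for the gcn2 response of total RNA, 247 to 390 for the difference, and 21 to 43 and 613 to 900 between genotypes. Polysomes gave 0 to 0 in wild type by limma, 612 to 1082 in gcn2 and 23 to 149 for the difference. Loading gave 0 to 0 in wild type and 0 to 7 in gcn2 by limma, 0 to 1 for the difference, 1 to 4 and 2 to 68 between genotypes, and 4824 to 6615 for the level.

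For named genes, 1850 values under the alternatives run for them kept direction and side of the threshold in 1547, lost the threshold in 297, gained it in 6 and changed direction in 0. Of 57 list calls, 55 passed with the block, 54 with median centring, 57 with the mean of a gene's probe sets, 11 with fry and 1 with an estimated correlation. Of 26 list calls in loading, 19 passed with small and 19 with large polysomes alone, and of 47 calls that use wild-type gradients or arrays, 35 passed without replicate 3, 6 did not pass and in 6 camera's direction relative to other genes changed, 2 of them with a change in the sign of the median.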

Other observations

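Both hypotheses in this part were tested only after their patterns were seen, and the values without wild-type replicate 3 were chosen after seeing the data.

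Without replicate 3, wild-type gradients after herbicide had a lower loading of 3 further gene lists by camera and a higher loading of 3 others. Plastid ribosomal protein mRNAs had a median of -0.54 (8 of 9 negative, adjusted p = 2.8e-06, and adjusted p = 0.071 with an estimated correlation) and histone mRNAs of -0.56 (8 of 8 negative, 2.8e-06 and 0.17). ATG8 mRNAs had a median of -0.60 (9 of 9 negative, 7e-06 and 0.17), while aminoacyl-tRNA synthetase mRNAs had a median of 0.42 (2 of 19 negative, 0.0039 and 0.26). Branched-chain amino acid breakdown had a median of 0.49 (0 of 6 negative, 0.012 and 0.43) and UDP-glycosyltransferases of 0.30 (13 of 47 negative, 0.015 and 0.43). Leaving out a pair that opposes the others raises a difference by construction, and these values rest on 2 gradients per arm.

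In wild-type polysomes without replicate 3, neighbouring glutaredoxin genes fell, AT4G15660 by 1.03, AT4G15680 by 1.33, AT4G15690 by 1.0 and AT4G15700 by 0.82. More broadly, neighbouring genes may rise together after herbicide. In gcn2 total RNA both genes rose in 41 of 5845 adjacent measured pairs, where 10000 permutations of the calls gave a mean of 22.1 (one-sided p = 2e-04). AT5G52750 with AT5G52760 and AT2G32020 with AT2G32030 were among them, and shared regulation and probes that bind both of 2 similar copies both stay open.

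Genes that differ between the 2 genotypes in mock may include differences between lines apart from GCN2. Of 24 called probe sets with a gene type, 8 (33.3%) belonged to genes that are not protein coding, against 7.39% of all probe sets with a gene type (one-sided Fisher p = 0.00022). The 8 were all pseudogenes, such as AT1G35650, AT1G35612 and AT2G04770. Whether they come from the line background or from the loss of GCN2 was not tested.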
